A study of Arabidopsis thaliana with 12 samples.

How the data were processed

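Gene expression was measured by RNA sequencing in mature rosette leaves of Arabidopsis thaliana Col-0 at plant ages of 29, 35, 42 and 57 d, with 3 libraries per age and 12 libraries in all. The submitters' labels describe Trizol extraction and Illumina TruSeq RNA v2 libraries, a poly(A)-selecting and unstranded kit, with 3 samples multiplexed per sequencing lane. The authors deposited raw read counts per gene for 33602 TAIR10 identifiers. The deposited counts are unnormalised whole numbers. The submitters' processing notes name TopHat2 2.0.4, Bowtie 0.12.8 and HTSeq, without settings and with no HTSeq version, on genome build TAIR10. Total counts ran from 19149874 in 42 d replicate 1 to 28772777 in 29 d replicate 3. A gene with 0 counts in a library was bounded by 3 counts of its total, and intervals on ratios are 95% counting intervals. These bounds and intervals cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

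Gene symbols, products and positions came from the TAIR10.1 annotation by locus identifier. Of 33323 nuclear identifiers, 32835 matched a record, and 10654 carry a symbol. Chloroplast and mitochondrial genes are given by identifier alone. For an unstranded count, reads over a stretch shared by 2 annotated genes cannot be assigned to one of them with certainty, so overlaps were looked up for each named nuclear gene.

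Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by the edgeR expression filter, libraries were scaled by trimmed mean of M values (TMM), and a quasi-likelihood model with 1 mean per age was fitted to all 12 libraries. The 3 steps between successive ages and the whole span from 29 to 57 d were tested. A further quasi-likelihood F-test covered any difference among the 4 ages. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Expression is given as edgeR's TMM-scaled CPM, as mean ± SD of 3 libraries. Fold changes are log2 values ± SE from the edgeR fit. The labels do not say whether the replicates came from separate plants, so the p-values measure the spread between the samples as sequenced. No pairing of samples by replicate number is stated, and the main fit assumed none. After the age means were removed, 6 of 18 pairs of libraries with the same number correlated above 0.1 (range -0.155 to 0.302). Among libraries of other ages, 6 of 12 libraries correlated best with one of their own number. These values cannot exclude pairing, and the replicate number as a block was an alternative.

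Before the data were examined, 35 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The lists were senescence markers, senescence transcription factors, chlorophyll breakdown, chlorophyll synthesis, Calvin cycle, light harvesting and photosystems, nitrogen remobilisation, autophagy, proteases, salicylic acid and defence, jasmonate, abscisic acid, ethylene, type-A cytokinin response regulators, cell cycle, phosphate starvation, anthocyanin and flavonoid, peroxisomal fatty acid breakdown, glucosinolate, scavenging of reactive oxygen species, histone H3 methylation and acetylation enzymes, flowering time and phase change, circadian clock, heat shock, reference genes, the NAC and WRKY families, cytosolic ribosomal proteins, chloroplast-encoded and mitochondrion-encoded genes, and markers of guard cells, phloem, xylem, epidermis and cuticle, and flowers and seeds. The NAC, WRKY, photosystem, ribosomal protein and organelle lists were drawn by rule from the annotation. SAG20 was left out of the senescence markers because the annotation names another gene at its written identifier. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 34 lists and the 4 comparisons. The flower and seed list had fewer than 3 tested members and was not tested as a list.

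The named genes are the 8 largest rises and the 8 largest falls per comparison among called genes with an average log2 CPM of at least 2 and CPM ranges that did not overlap between the 2 ages. From each list, the 2 called members that rose most and the 2 that fell most were added, or the member with the smallest p where none was called. SAG12, ORE1, NAP, WRKY53, SGR1, RBCS1A and CAB1 are given at every age.

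The procedure was tested on simulated data with known changes. At a true 2-fold change, 75%, 70%, 69% and 71% of 100 changed genes were recovered in the 4 comparisons in the order given above. At a true 4-fold change the shares were 97%, 94%, 97% and 98%, with 10, 11, 12 and 8 false calls. DESeq2 made 51, 55, 48 and 37 false calls on the same data. It called 88, 84, 87 and 79 of the 100 genes changed 2-fold, without a check of direction.

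The alternatives were relative log expression factors, DESeq2 1.42.0, no expression filter, a higher expression minimum, organelle genes left out, only the 6 libraries of the ages compared, the replicate number as a block, an estimated inter-gene correlation, the fry set test, and each library left out in turn. Leaving out the nuclear ribosomal RNA genes, and leaving 57 d replicate 2 out of the comparisons that do not hold 57 d, were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.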

Results

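Messenger RNA was counted per gene in mature rosette leaves, described in the labels as predominantly mesophyll, of Arabidopsis plants aged 29, 35, 42 and 57 d. Each age had 3 libraries (n = 3 throughout), with total counts of 19149874 to 28772777 per library. The series concerns developmental leaf senescence, the programmed breakdown of the leaf with age, and the steps between ages ask which genes change as the leaf grows old. Of 19513 genes tested, 14719 (75.4%) differed among the 4 ages in edgeR.

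The first 2 principal components held 68.6% and 15.5% of the variance. The 29 d libraries lay apart from the rest on the first component. Within an age, Pearson's r between libraries across genes was 0.987 to 0.989 at 29 d, 0.980 to 0.988 at 35 d, 0.983 to 0.985 at 42 d and 0.959 to 0.983 at 57 d. Genes are not independent replicates in these correlations. The biological coefficient of variation was 0.127, 0.170, 0.163 and 0.297 at the 4 ages in order. The spread at 57 d was 1.74 times the next highest, and 1.21 times without 57 d replicate 2. That library stood at 13 on the second component, against 80.7 and 65.2 for replicates 1 and 3 and -33.6 to -9.55 for the 42 d libraries. Its r was 0.963 to 0.967 with the 42 d libraries, against 0.959 and 0.969 with 57 d replicates 1 and 3.

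**Figure D1:**
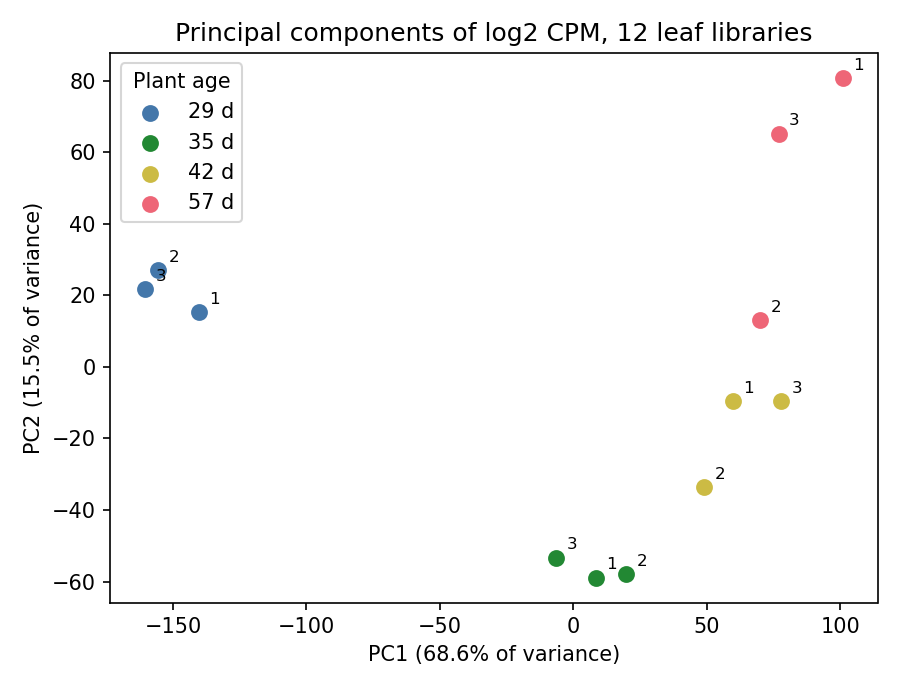
First and second principal components (68.6% and 15.5% of the variance) of log2 CPM, one point per library, coloured by plant age and labelled by replicate number. The 3 libraries at 29 d lie at the left, and 57 d replicate 2 lies at 13 on the vertical axis, below the other 57 d libraries.

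SAG12, a cysteine protease gene widely used as a marker of late leaf senescence (AT5G45890, TAIR10.1 chromosome 5, 18613239 to 18614963), had a mean of 0.0341 ± 0.0591 CPM (SD, n = 3) at 29 d, 0.199 ± 0.345 at 35 d, 6.06 ± 4.91 at 42 d and 88.0 ± 90.3 at 57 d. SGR1, which encodes a magnesium dechelatase of chlorophyll breakdown (AT4G22920, chromosome 4, 12016420 to 12018643), stood at 62.5 ± 13.6, 153 ± 16.8, 218 ± 28.9 and 232 ± 120 CPM at the same ages. WRKY53, a transcription factor of early senescence (AT4G23810), had 73.9 ± 44.0, 818 ± 211, 477 ± 28.0 and 880 ± 561 CPM. The NAC factors ORE1 (AT5G39610) and NAP (AT1G69490), both promoters of senescence, were no lower on average at 29 d than at 35 d. ORE1 had 118 ± 6.10, 62.9 ± 16.0, 119 ± 11.5 and 118 ± 61.9 CPM, and NAP had 194 ± 26.5, 186 ± 40.2, 199 ± 22.9 and 217 ± 143 CPM.

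The chlorophyll a/b-binding protein gene CAB1 (AT1G29930, chromosome 1, 10477885 to 10479114) had 23652 ± 5230 CPM at 29 d, 4036 ± 298 at 35 d, 2387 ± 795 at 42 d and 3474 ± 1551 at 57 d. RBCS1A, a gene for the small subunit of Rubisco (AT1G67090), had 2395 ± 502, 742 ± 79.3, 449 ± 132 and 552 ± 225 CPM. CAB and RBCS genes have close copies, so the share of reads that belongs to each copy is uncertain. CAB1 and WRKY53 also overlap another annotated gene. At 57 d, replicate 2 held 1.10 CPM of SAG12 against 181 and 81.8 in replicates 1 and 3, and 46.2 CPM of ORE1 against 151 and 155.

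**Figure D2:**
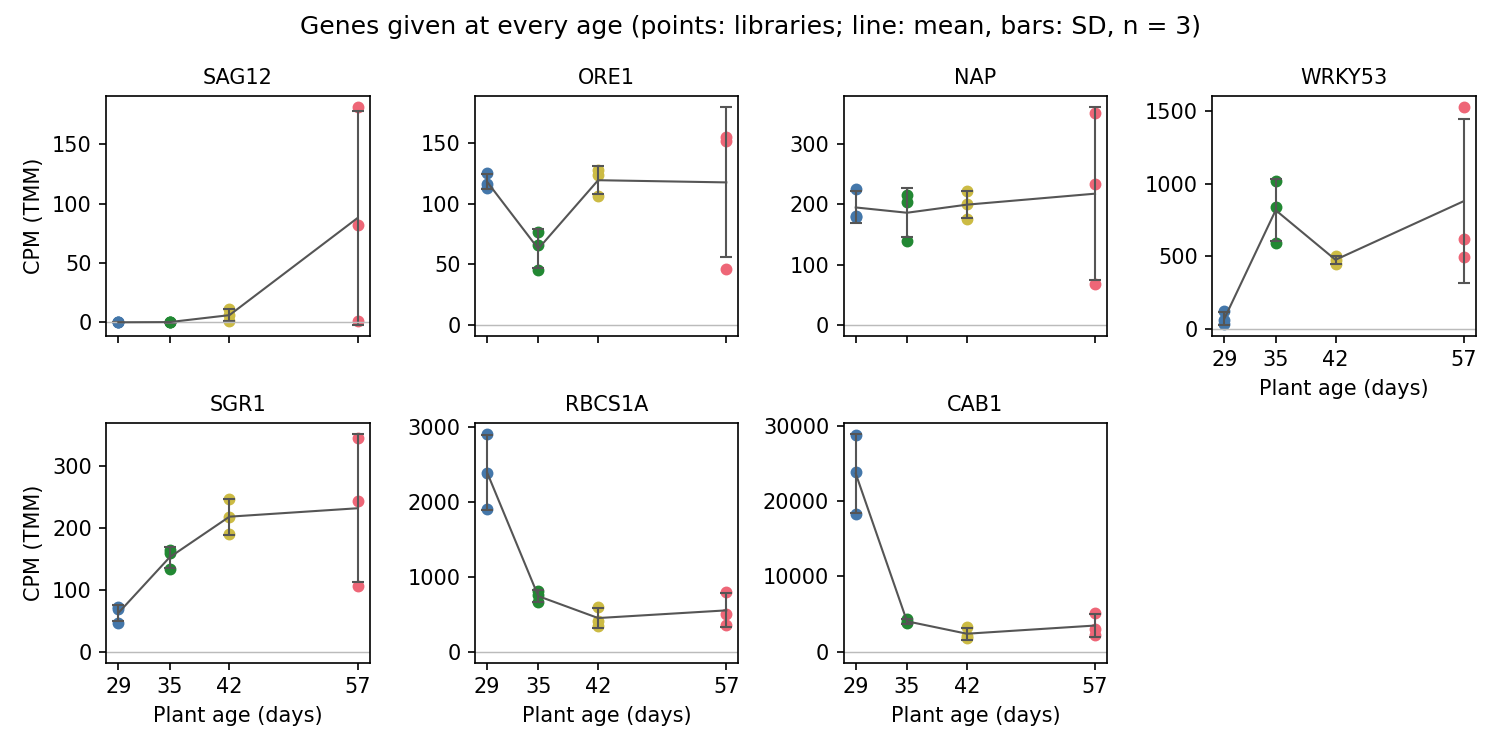
TMM-scaled CPM (vertical axis, linear) of the 7 genes given at every age against plant age in days, with points for libraries, a line through the means and bars for SD (n = 3). SAG12 reached 181 and 81.8 CPM in replicates 1 and 3 at 57 d and 1.10 in replicate 2, and CAB1 fell from a mean of 23652 CPM at 29 d to 4036 at 35 d.

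**Figure D3:**
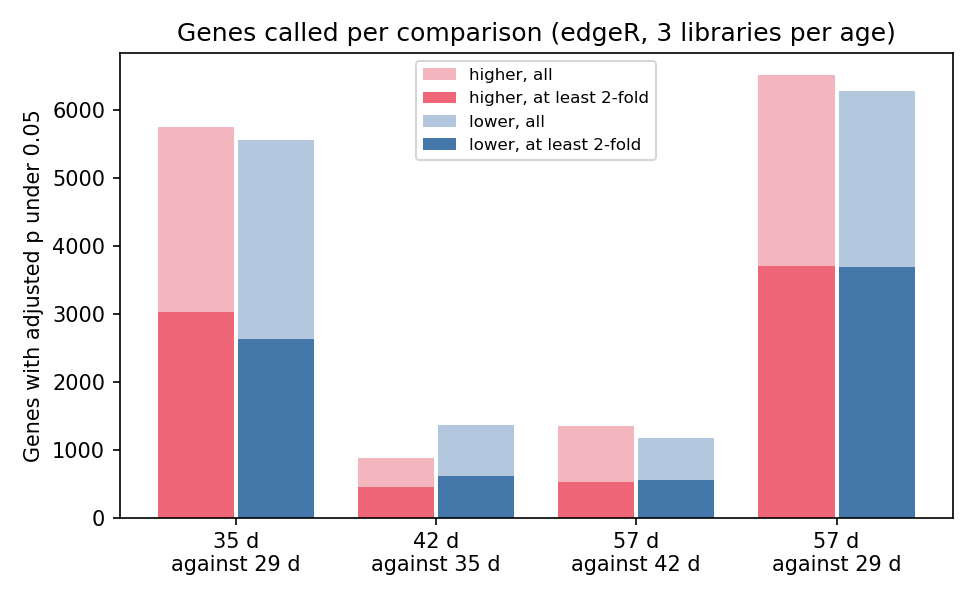
Number of genes with an edgeR adjusted p under 0.05 (vertical axis) in each comparison, higher (red) or lower (blue) at the later age, with the part that changed at least 2-fold in the darker shade. The span from 29 to 57 d had 6518 higher and 6285 lower genes.

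From 29 to 35 d, most photosystem genes fell, and most jasmonate genes and all tested glucosinolate genes rose. Of 49 tested genes of light harvesting and the photosystems, 42 fell and none rose, with a list median of -1.84 on the log2 scale. Of 16 jasmonate genes, 13 rose and none fell, with a median of 2.76. LOX3, a lipoxygenase of jasmonate synthesis (AT1G17420, chromosome 1, 5977323 to 5981521), rose from 3.43 ± 2.01 to 549 ± 321 CPM, a log2 fold change of 7.34 ± 0.80 (SE, edgeR adjusted p = 1.93e-05). Its relative LOX4 (AT1G72520) rose by 7.18 ± 0.96, from 4.68 ± 4.71 to 667 ± 406 CPM. XTH15, a xyloglucan endotransglucosylase of the growing wall (AT4G14130, chromosome 4, 8137020 to 8138392, overlapping AT4G14120), fell by 7.78 ± 0.67 on the log2 scale, from 650 ± 325 to 2.96 ± 0.824 CPM.

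The other large rises from 29 to 35 d included FAMT, a farnesoic acid methyltransferase gene (AT3G44860, chromosome 3, 16379571 to 16381434), at 8.25 ± 0.61, and the jasmonate repressor gene JAZ8, which had 2 counts at 29 d and a ratio of 258 (95% counting interval 71.2 to 2139). AT5G28610, annotated as similar to an RNA helicase, had no counts at 29 d and was at least 152-fold higher at 35 d, against a floor of 3 counts over the 3 libraries. Among the largest falls, the fatty acid desaturase gene ADS1 fell by 7.55 ± 0.70, and the gibberellin-responsive gene GASA4 fell by 7.36 ± 0.49. XTH8 fell by 6.66 ± 0.46, and the auxin synthesis gene YUC8 fell by 6.43 ± 0.56. Of 11 tested cell cycle genes, 7 fell and 1 rose. CDC6, a licensing factor of DNA replication, fell by 3.87 ± 0.38.

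Among photosynthesis genes at 35 d, LHB1B1, another chlorophyll a/b-binding protein gene, fell by 3.03 ± 0.28, from 9508 ± 1611 to 1166 ± 258 CPM. Of 20 Calvin cycle genes, 17 fell and 1 rose (median -0.98), and the phosphoribulokinase gene PRK fell by 2.63 ± 0.20. Camera at the preset correlation called the photosystem list (adjusted p = 5.39e-20) and the Calvin cycle list (adjusted p = 1.88e-05), with adjusted p = 0.476 and adjusted p = 0.524 with an estimated correlation. Chlorophyll synthesis genes fell in 13 of 23 cases and rose in 3. Cytosolic ribosomal protein genes fell in 181 of 273 cases and rose in 15 (median -0.60, camera adjusted p = 1.15e-08, adjusted p = 0.578 with an estimated correlation). The list was drawn from annotated product names, so it also holds some proteins of organelle ribosomes. AT1G29070, the member that fell most, encodes ribosomal protein L34 of the bacterial type found in plastids, and it fell by 2.30 ± 0.17.

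On the rising side, all 13 tested glucosinolate genes rose (median 2.23, camera adjusted p = 2.1e-05, adjusted p = 0.476 with an estimated correlation). CYP83B1, a cytochrome P450 of indole glucosinolate synthesis, rose by 3.92 ± 0.35, to 1150 ± 252 CPM. For the jasmonate list the camera adjusted p was 6.78e-07, and adjusted p = 0.476 with an estimated correlation. Of 17 genes of salicylic acid and defence, 10 rose and none fell (median 1.27, camera adjusted p = 0.00578, adjusted p = 0.578 with an estimated correlation). PR2, a pathogenesis-related glucanase gene, rose by 3.84 ± 0.44. The WRKY family had 31 genes up and 2 down of 54 (camera adjusted p = 0.000133, adjusted p = 0.476 with an estimated correlation). The NAC family had 31 up and 9 down of 59 (camera adjusted p = 0.00164, adjusted p = 0.506 with an estimated correlation). WRKY55 rose by 6.11 ± 0.73 and NAC090 by 5.66 ± 0.65.

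Senescence genes went both ways at this step. Of 20 senescence transcription factors, 11 rose and 2 fell (camera adjusted p = 0.00459, adjusted p = 0.578 with an estimated correlation). WRKY53 rose by 3.47 ± 0.50, and ORE1 fell by 0.91 ± 0.36 (edgeR adjusted p = 0.0459). The call on ORE1 was lost when any single library of the 6 other than 35 d replicate 3 was left out. NAP changed by -0.07 ± 0.42 and SAG12 by 2.38 ± 4.43, neither called. Of 13 senescence markers, 5 rose and 2 fell (camera adjusted p = 0.472, adjusted p = 0.796 with an estimated correlation). SAG113, a protein phosphatase gene, rose by 2.84 ± 0.52, and SEN1, a gene induced by darkness, fell by 1.7 ± 0.25, from 8804 ± 480 to 2707 ± 580 CPM. Among 20 genes of nitrogen remobilisation, 10 rose and 6 fell. The cytosolic glutamine synthetase gene GLN1;1 rose by 2.13 ± 0.20, and the asparagine synthetase gene ASN1 fell by 1.65 ± 0.34.

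Markers of other leaf cell types moved at this step too. Of 9 epidermis and cuticle markers, 7 fell and none rose (camera adjusted p = 0.0436, adjusted p = 0.623 with an estimated correlation), and the lipid transfer protein gene LTP1 fell by 4.27 ± 0.64. All 6 tested xylem markers fell (camera adjusted p = 0.0456, adjusted p = 0.623 with an estimated correlation). Of 9 guard cell markers, 2 rose and 2 fell. The 2 that fell, TGG1 and TGG2, encode myrosinases, which hydrolyse glucosinolates. TGG1 fell by 3.55 ± 0.38, and TGG2 fell by 2.33 ± 0.42. Of 51 tested mitochondrion-encoded genes, 41 rose and none fell (median 1.26, camera adjusted p = 4.48e-06, adjusted p = 0.476 with an estimated correlation). The mitochondrial share of all counts was 0.0215% to 0.0244% at 29 d and 0.0421% to 0.0686% at 35 d. The nuclear ribosomal RNA share was 0.596% to 0.700% at 29 d and 0.701% to 1.37% at 35 d, and the chloroplast share was 0.853% to 1.11% and 1.13% to 2.58%. All of these shares were highest in 35 d replicate 1 and lowest in 35 d replicate 3. The kit selects poly(A) RNA, so more of these RNAs passing the selection cannot be told apart from a change in expression.

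In all, 11308 genes were called between 29 and 35 d, of which 5747 were higher and 5561 lower at 35 d, and 5669 changed at least 2-fold. DESeq2 called 5645 higher and 5987 lower, and relative log expression factors gave 5521 higher and 5781 lower. Adjusted over the list alone, the counts just given were the same, except 183 fallen ribosomal protein genes, 7 fallen nitrogen genes, 35 risen NAC genes, 3 fallen WRKY genes and 1 risen guard cell marker. Of 126 named genes called, 21 lost the call when some single library was left out, each such library ending 7 to 14 calls. Camera called 12 of 34 lists at the preset correlation and none with an estimated one (3 at an unadjusted p under 0.05). Lists given for this step without a camera p were not called. Fry called 23, and other splits of the same 6 libraries gave up to 14 camera calls. Such splits, here and in the comparisons below, keep part of the difference between the ages. They do not show how many lists chance would call.

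**Figure D4:**
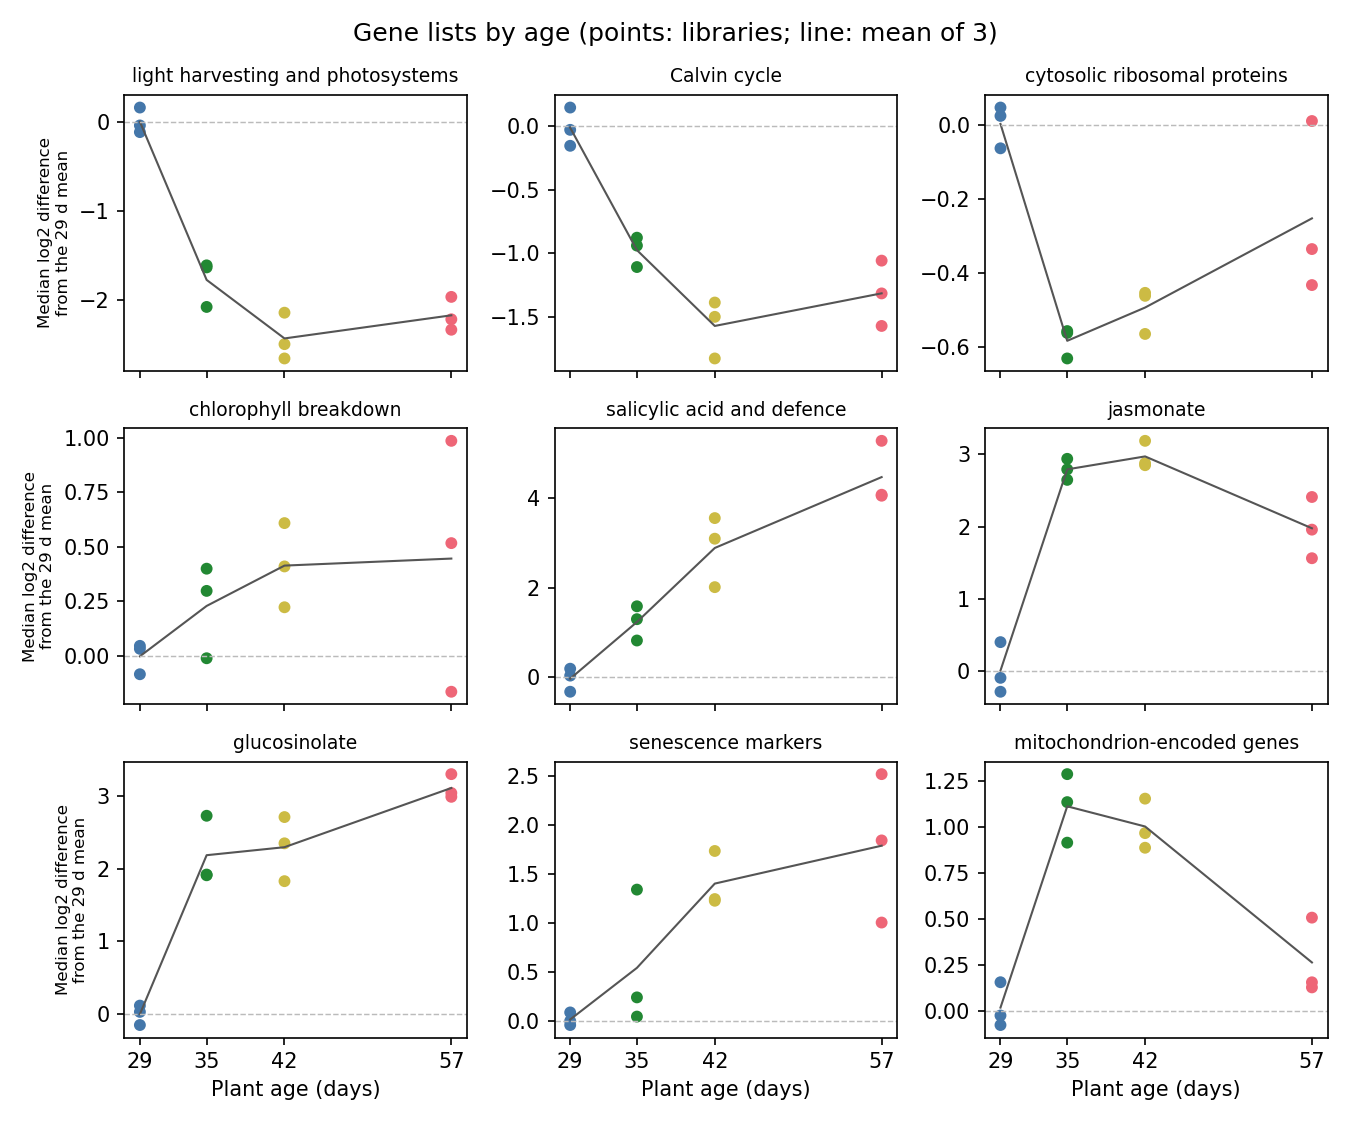
Median over the tested members of 9 gene lists of the log2 difference from the 29 d mean (vertical axis), against plant age in days, with points for libraries and lines through the means of 3. Photosystem and Calvin cycle genes lay below 0 from 35 d on, and the medians of salicylic acid and defence genes lay highest at 57 d.

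From 35 to 42 d, some photosystem genes fell and some senescence transcription factors rose. Of 49 photosystem genes, 22 fell and none rose (33 fell adjusted over the list alone), with a list median of -0.65. LHB1B1 fell by 1.57 ± 0.26, from 1166 ± 258 to 392 ± 137 CPM. Of 20 senescence transcription factors, 9 rose and none fell (13 rose adjusted over the list alone). SRG1, a senescence-related oxidoreductase gene (AT1G17020, chromosome 1, 5820080 to 5822013), rose by 2.07 ± 0.37, from 8.85 ± 3.51 to 37.0 ± 14 CPM. NAC047, a NAC factor gene (AT3G04070, chromosome 3, 1061300 to 1063234), rose by 2.97 ± 0.34, from 9.12 ± 1.83 to 71.5 ± 19.8 CPM.

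Camera at the preset correlation called the photosystem list (adjusted p = 6.21e-15) and the senescence transcription factors (adjusted p = 9.79e-08), with adjusted p = 0.506 and adjusted p = 0.476 with an estimated correlation. Senescence markers rose in 2 of 13 cases (5 adjusted over the list alone, camera adjusted p = 0.00341, adjusted p = 0.476 with an estimated correlation). SAG12 changed by 5.0 ± 1.81 (edgeR adjusted p = 0.0937). DIN2, a beta-glucosidase gene induced in the dark, rose by 6.03 ± 1.06, from 1.12 ± 1.03 to 71.5 ± 77.8 CPM. PR1, the classic marker of salicylic acid signalling (AT2G14610, chromosome 2, 6241640 to 6242541), rose by 6.08 ± 1.32, and 5 of 17 genes of salicylic acid and defence rose (11 adjusted over the list alone, camera adjusted p = 0.000581, adjusted p = 0.578 with an estimated correlation). The call on PR1 was lost without 35 d replicate 1, 2 or 3 or 42 d replicate 3.

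The myrosinase gene TGG2 fell by 5.49 ± 0.49, and TGG1 fell by 2.75 ± 0.37. They were 2 of the 3 guard cell markers that fell, of 9. The potassium channel gene KAT1 rose by 0.55 ± 0.12, a call lost without 35 d replicate 1 or 3 or 42 d replicate 1. For the guard cell list the camera adjusted p was 0.00985, and adjusted p = 0.578 with an estimated correlation. Of 6 xylem markers, 4 fell (median -2.96, camera adjusted p = 1.49e-05, adjusted p = 0.476 with an estimated correlation). XCP2, a xylem cysteine protease gene (AT1G20850), fell by 3.84 ± 0.58, from 2.74 ± 0.914 to 0.185 ± 0.0807 CPM. Of 9 epidermis and cuticle markers, 3 fell (7 adjusted over the list alone, camera adjusted p = 0.00364, adjusted p = 0.567 with an estimated correlation). SPL3, a phase change factor gene that overlaps AT2G33815, fell by 1.59 ± 0.25. MES16, a methylesterase gene of chlorophyll breakdown, rose by 1.66 ± 0.29, the 1 called gene of 14 in its list.

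In all, 2240 genes were called between 35 and 42 d, with 874 higher and 1366 lower at 42 d, and 1053 changed at least 2-fold. The count was 557, 1474 and 512 without 35 d replicate 1, 2 or 3, 836 and 330 without 42 d replicate 1 or 3, and 3748 without 57 d replicate 2. The excess of lower genes ended without 42 d replicate 2, with 866 higher and 860 lower, and at least 2-fold it turned, with 543 higher and 493 lower. DESeq2 called 1542 higher and 1728 lower. The 2-fold count was 390, 324, 527 and 227 without 35 d replicate 1, 35 d replicate 3, 42 d replicate 1 or 42 d replicate 3. Of 66 named genes called, 49 lost the call when some library was left out. SRG1, NAC047, LHB1B1, DIN2, TGG1, TGG2, XCP2, SPL3 and MES16 were called in all 6 fits that left out a 35 or 42 d library. Camera called 13 of 34 lists at the preset correlation and none with an estimated one (1 at an unadjusted p under 0.05). Fry called 14, and other splits of the same 6 libraries gave up to 16 camera calls.

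From 42 to 57 d, some salicylic acid and defence genes rose and some jasmonate genes fell. Of 17 genes of salicylic acid and defence, 9 rose and none fell (11 rose adjusted over the list alone), with a median of 1.94. FMO1, a monooxygenase gene of systemic immunity (AT1G19250, chromosome 1, 6650476 to 6653195), rose by 4.12 ± 0.90, from 1.61 ± 1.25 to 28.0 ± 24.8 CPM. Of 16 jasmonate genes, 7 fell and none rose (9 fell adjusted over the list alone), with a median of -1.31. AOC2, an allene oxide cyclase gene of jasmonate synthesis (AT3G25770, chromosome 3, 9406669 to 9408071), fell by 2.66 ± 0.27, from 172 ± 63.5 to 27.2 ± 6.27 CPM.

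The camera adjusted p was 2.75e-08 for salicylic acid and defence and 9.98e-09 for jasmonate, with adjusted p = 0.476 for both with an estimated correlation. CYP82C2, a cytochrome P450 gene of indole-derived defence compounds (AT4G31970, chromosome 4, 15462350 to 15464563), rose by 8.42 ± 0.53, from 0.0805 ± 0.107 to 26.8 ± 8.03 CPM. CHX17, a cation/proton exchanger gene (AT4G23700), rose by 4.28 ± 0.48, from 8.39 ± 3.54 to 163 ± 90.0 CPM. WRKY75, a WRKY factor that promotes senescence (AT5G13080), rose by 3.04 ± 0.47, and JUB1, a NAC factor reported to delay it (AT2G43000, overlapping AT2G42990), rose by 3.32 ± 0.44. The stress-responsive NAC gene RD26 fell by 1.52 ± 0.33. Of 14 protease genes, 3 rose and none fell (4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00371, adjusted p = 0.476 with an estimated correlation), and the metacaspase gene MC2 rose by 1.34 ± 0.15. Relative to the 29 d mean, the protease median was 0.336 in 57 d replicate 2, against 1.18 and 0.820 in replicates 1 and 3. The 42 d libraries stood at 0.337 to 0.691. SAG12 changed by 3.88 ± 1.23 (edgeR adjusted p = 0.0616), and by 4.46 without 57 d replicate 2, where it was called.

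Of 51 mitochondrion-encoded genes, 16 fell and none rose (25 fell adjusted over the list alone, camera adjusted p = 1.64e-10, adjusted p = 0.476 with an estimated correlation). Of 87 chloroplast-encoded genes, 21 fell and 1 rose (36 fell adjusted over the list alone, camera adjusted p = 1.23e-09, adjusted p = 0.524 with an estimated correlation). In the 42 d libraries nuclear ribosomal RNA took 1.03% to 1.85% of all counts, chloroplast genes 1.17% to 2.26% and mitochondrial genes 0.0386% to 0.0598%. At 57 d these shares were 0.733% to 1.27%, 0.513% to 1.02% and 0.0230% to 0.0394%. They were all highest in 57 d replicate 2 and lowest in 57 d replicate 1. Here too, passage through the poly(A) selection cannot be told apart from expression. Cytosolic ribosomal protein genes rose in 33 of 273 cases and fell in 1 (camera adjusted p = 8.85e-06, adjusted p = 0.673 with an estimated correlation). Their list median, relative to the 29 d mean, was 0.0105 in 57 d replicate 2 and -0.433 and -0.336 in replicates 1 and 3. At 42 d it was -0.565 to -0.454. Photosystem genes rose in 6 of 49 cases and none fell (7 rose adjusted over the list alone, camera adjusted p = 0.043, adjusted p = 0.796 with an estimated correlation). Their list median on the same scale was -1.97 in 57 d replicate 2 and -2.34 and -2.22 in replicates 1 and 3. At 42 d it was -2.66 to -2.15. LHCB4.3, a light-harvesting gene, rose by 1.40 ± 0.27.

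Among the largest falls, MLP28, a major latex protein gene, fell by 4.40 ± 0.47. The largest falls also included 4 genes known as pollen genes. VGD1, a pectin methylesterase gene, fell by 3.14 ± 0.73, and its relative VGDH1 fell by 3.16 ± 0.74. AT3G01270, a pectate lyase family gene, fell by 3.27 ± 0.71, and the multicopper oxidase-like gene sks13 fell by 3.18 ± 0.66. The call on sks13 held in all 6 fits that left out a library, that on AT3G01270 was lost without 57 d replicate 3, and those on VGD1 and VGDH1 were lost without any of 42 d replicates 2 and 3 and 57 d replicates 1 and 3. Xylem markers rose in 2 of 6 cases (5 adjusted over the list alone, camera adjusted p = 0.00162, adjusted p = 0.527 with an estimated correlation), and XCP2 rose by 3.53 ± 0.59, to 2.23 ± 1.19 CPM. Guard cell markers fell in 4 of 9 cases and rose in 1 (7 fell adjusted over the list alone, camera adjusted p = 0.00341, adjusted p = 0.552 with an estimated correlation). TGG2 fell by 2.52 ± 0.53, and KAT1 rose by 0.96 ± 0.12.

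In all, 2532 genes were called between 42 and 57 d, with 1352 higher and 1180 lower at 57 d, and 1085 changed at least 2-fold. The count was 1368, 1102 and 1397 without 42 d replicate 1, 2 or 3 and 4422 without 57 d replicate 2, and the 2-fold count was 609 without 42 d replicate 2 and 1942 without 57 d replicate 2. With the 6 libraries of these ages alone, 498 genes were called, 227 higher and 271 lower. The balance also turned without 42 d replicate 1, with 630 higher and 738 lower, and was even without 42 d replicate 2, with 553 and 549. It was 1067 higher and 637 lower without 57 d replicate 3. Of 76 named genes called, 47 lost the call when some library was left out. CYP82C2, CHX17, WRKY75, JUB1, RD26, FMO1, AOC2, MC2, MLP28, XCP2, TGG2, KAT1 and LHCB4.3 kept it in all 6 such fits. Camera called 13 of 34 lists at the preset correlation, none with an estimated one (3 at an unadjusted p under 0.05), and up to 19 in other splits of these libraries, and fry called 12.

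Over the whole span from 29 to 57 d, salicylic acid and defence genes and most senescence markers rose, and most photosystem genes and all tested epidermis markers fell. All 17 tested genes of salicylic acid and defence rose, with a median of 4.98. PR1 rose by 11.12 ± 1.5, from 0.0596 ± 0.0122 to 148 ± 145 CPM. SAG12 rose by 11.25 ± 2.19, and, with 2 counts at 29 d, its ratio was 2945 (95% counting interval 815 to 24319). Of 49 photosystem genes, 46 fell and 1 rose, with a median of -2.15. XTH15 fell by 11.73 ± 0.84, to 0.191 ± 0.258 CPM.

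Of 13 senescence markers, 10 rose and 2 fell (camera adjusted p = 0.0963, adjusted p = 0.602 with an estimated correlation). SAG13, a short-chain dehydrogenase gene, rose by 9.03 ± 1.27, and SEN1 fell by 2.02 ± 0.25. Of 20 senescence transcription factors, 15 rose and none fell (camera adjusted p = 1.4e-05, adjusted p = 0.476 with an estimated correlation). WRKY75 rose by 8.48 ± 0.67, from 0.425 ± 0.0907 to 151 ± 91.6 CPM. WRKY53 rose by 3.57 ± 0.50, with 1523 CPM in 57 d replicate 2 against 494 and 621 in replicates 1 and 3. ORE1 and NAP were not called, at -0.01 ± 0.35 and 0.16 ± 0.42. Without 57 d replicate 2, NAP rose by 0.59 ± 0.21 (edgeR adjusted p = 0.0296), and ORE1 changed by 0.38 ± 0.18 (edgeR adjusted p = 0.0816). The NAC family had 41 genes up and 5 down of 59, and the WRKY family had 38 up and 2 down of 54. Their camera adjusted p-values were 5.48e-06 and 7.48e-07, with adjusted p = 0.476 for both with an estimated correlation.

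The largest rises over the span also included OSM34, an osmotin-like defence gene (AT4G11650), with 1 count at 29 d and 112 ± 85.4 CPM at 57 d, a ratio of 7434 (95% counting interval 1334 to 293658). CYP82C2 had no counts at 29 d and was at least 582-fold higher at 57 d. For salicylic acid and defence the camera adjusted p was 6.78e-07, and adjusted p = 0.476 with an estimated correlation. Jasmonate genes rose in 12 of 16 cases and fell in 1 (camera adjusted p = 0.00704, adjusted p = 0.578 with an estimated correlation). LOX3 stood at 347 CPM in 57 d replicate 2 against 121 and 58.9 in replicates 1 and 3. Glucosinolate genes rose in 11 of 13 cases and fell in 1 (camera adjusted p = 0.00032, adjusted p = 0.476 with an estimated correlation). Phosphate starvation genes rose in 5 of 9 cases, with PLDZ2, a phospholipase D gene that overlaps AT3G05640, at 4.61 ± 0.39. Relative to the 29 d mean, their median was 0.175 in 57 d replicate 2, against 1.42 and 1.77 in replicates 1 and 3.

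Genes of leaf breakdown and recycling went both ways, as did all 19513 tested genes, of which 6518 rose and 6285 fell. Of 14 chlorophyll breakdown genes, 6 rose and 4 fell (camera adjusted p = 0.472, adjusted p = 0.839 with an estimated correlation), with SGR2 at 3.14 ± 0.28. Relative to the 29 d mean, the list median was -0.166 in 57 d replicate 2, against 0.985 and 0.516 in replicates 1 and 3. Of 20 nitrogen remobilisation genes, 10 rose and 3 fell (camera adjusted p = 0.0231, adjusted p = 0.476 with an estimated correlation), and the nitrate transporter gene NRT1.5, which overlaps AT1G32440, rose by 3.68 ± 0.38. Of 14 proteases, 10 rose and 3 fell (camera adjusted p = 0.0468, adjusted p = 0.552 with an estimated correlation). Of 34 autophagy genes, 12 rose and 7 fell (camera adjusted p = 0.591, adjusted p = 0.898 with an estimated correlation). ATG7 was up by 2.43 ± 0.44 and ATG4a, which overlaps AT2G44130, down by a log2 value of -1.60 ± 0.16. The autophagy median was -0.234 in 57 d replicate 2, against 0.442 and 0.308 in replicates 1 and 3. Of 14 genes of peroxisomal fatty acid breakdown, 10 rose and 1 fell (camera adjusted p = 0.0630, adjusted p = 0.722 with an estimated correlation). Those that rose most, PES1 at 4.51 ± 0.83 and PES2 at 4.23 ± 0.26, encode phytyl ester synthases of the chloroplast, which esterify fatty acids with phytol from chlorophyll.

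On the falling side, the photosystem list had a camera adjusted p of 1.71e-20, and adjusted p = 0.476 with an estimated correlation. Calvin cycle genes fell in 16 of 20 cases (camera adjusted p = 8.85e-06, adjusted p = 0.524 with an estimated correlation). Chlorophyll synthesis genes fell in 13 of 23 cases and rose in 2 (camera adjusted p = 0.0361, adjusted p = 0.602 with an estimated correlation). Ribosomal protein genes fell in 106 of 273 cases and rose in 23 (camera adjusted p = 0.0289, adjusted p = 0.796 with an estimated correlation). Their list median, relative to the 29 d mean, was 0.0105 in 57 d replicate 2 and -0.433 and -0.336 in replicates 1 and 3. Chloroplast-encoded genes fell in 36 of 87 cases and rose in 1 (camera adjusted p = 0.0132, adjusted p = 0.736 with an estimated correlation), and mitochondrion-encoded genes rose in 9 of 51 cases and fell in 4. The limit set by the poly(A) selection holds for these organelle genes over the span as well. All 9 epidermis and cuticle markers fell (camera adjusted p = 0.000581, adjusted p = 0.518 with an estimated correlation), with LTP1 down from 1126 ± 85.8 to 13.3 ± 8.64 CPM. All 6 xylem markers fell (camera adjusted p = 0.0456, adjusted p = 0.623 with an estimated correlation). Guard cell markers fell in 6 of 9 cases and rose in 1, and TGG2 fell by 10.34 ± 0.62, from 845 ± 164 to 0.653 ± 0.523 CPM. Phloem markers rose in 2 of 6 cases and fell in 1. Of the flower and seed markers only SEP3 passed the expression filter, at 1.43 ± 0.48, from 0.196 ± 0.113 to 0.514 ± 0.176 CPM, a call lost without 29 d replicate 2 or 3 or 57 d replicate 2.

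Ethylene genes rose in 7 of 14 cases and fell in 4. The ACC synthase gene ACS2 rose by 7.91 ± 0.87, and its relative ACS8 fell by 3.63 ± 0.19. The median of the ethylene list was 0.41 while camera ranked the list down (adjusted p = 0.827). Abscisic acid genes rose in 5 of 15 cases and fell in 2. Type-A cytokinin response regulators fell in 4 of 7 cases and none rose, with ARR9 down by a log2 value of -3.13 ± 0.41. Cell cycle genes fell in 3 of 11 cases and rose in 1. Enzymes that methylate, demethylate, acetylate or deacetylate histone H3 rose in 10 of 25 cases and fell in 5. The demethylase genes JMJ18 and JMJ16, which both overlap a neighbouring gene, rose by 1.30 ± 0.20 and 0.98 ± 0.10. Log2 changes in this list ran from -2.71 to 1.30, with a median of -0.00305.

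Of 9 genes of flowering time and phase change, 2 rose and 3 fell. FT, the florigen gene, rose by 4.79 ± 0.76, and SPL3 fell by 3.10 ± 0.26. Of 13 circadian clock genes, 3 rose and 5 fell. Heat shock genes rose in 5 of 6 cases and fell in 1, with HSP90.1 at 3.01 ± 0.35. Of 7 anthocyanin and flavonoid genes, 2 rose and 4 fell. The regulators PAP1 and PAP2 had no counts at 29 d and were at least 13-fold and 12.8-fold higher at 57 d, and chalcone synthase (CHS), which overlaps AT5G13940, fell by 5.98 ± 0.60. The list median was -0.93. Of 9 genes that scavenge reactive oxygen species, 2 rose and 5 fell. The catalase gene CAT2, which overlaps AT4G35080, fell by 2.64 ± 0.18. Of 11 reference genes, 2 rose and 2 fell, with GAPC1 at 1.16 ± 0.16 and ACT2 at -0.58 ± 0.12.

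In all, 12803 genes were called between 29 and 57 d, with 6518 higher and 6285 lower at 57 d, and 7404 changed at least 2-fold. Adjusted over the list alone, the list counts over this span were the same, except 47 fallen photosystem genes, 21 risen and 94 fallen ribosomal protein genes, 34 fallen chloroplast-encoded genes, 5 risen and 2 fallen mitochondrion-encoded genes, 2 risen and 4 fallen clock genes, and 2 fallen genes of peroxisomal fatty acid breakdown. Of 128 named genes called, 10 lost the call when some library was left out. Camera called 15 of 34 lists at the preset correlation, none with an estimated one (3 at an unadjusted p under 0.05), and up to 18 in other splits of these libraries, and fry called 27. Tested lists given for this span without a camera p were not called.

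The first and last steps had a correlation near 0. Across the 19513 genes, the log2 changes from 29 to 35 d and from 42 to 57 d correlated at a Pearson's r of -0.067 and a Spearman's rho of -0.063, and genes are not independent here. With an average log2 CPM of at least 2 required, r was 0.0438. Of 1180 genes that fell at the last step, 533 had risen at the first, against 348 if the steps were independent, and 334 had fallen, against 336. Of 1352 genes that rose at the last step, 392 had risen at the first, against 398, and 452 had fallen, against 385.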

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

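Among the alternatives, leaving out the nuclear ribosomal RNA genes, and leaving 57 d replicate 2 out of the comparisons without 57 d, were chosen after the data were seen. Counts of genes are given in the order 35 against 29 d, 42 against 35 d, 57 against 42 d and 57 against 29 d. With relative log expression factors, DESeq2, no filter, organelle or ribosomal RNA genes left out, or replicate number as a block, each total stayed within 1.5 times its main value, while the genes higher at 42 than at 35 d went from 874 to 1542 with DESeq2. DESeq2 called 11632, 3270, 3406 and 13408 genes, and in the simulated data it made 51, 55, 48 and 37 false calls against 10, 11, 12 and 8 with edgeR. Of 100 genes changed 2-fold in the simulated data, it called 88, 84, 87 and 79, and edgeR recovered 75, 70, 69 and 71. Those data held few changed genes and the same spread at all ages, unlike the real libraries. The fit with the replicate number as a block called 11325, 2329, 2433 and 12829 genes, 5659, 1064, 1054 and 7386 at least 2-fold, 14643 across the ages, and 11, 13, 11 and 15 lists, with r = -0.0885 between the first and last steps.

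The middle steps depended on single libraries. Leaving each out in turn gave 9684 to 12318, 330 to 3748, 1102 to 4422 and 11700 to 13391 genes, the lowest of the middle steps without 42 d replicate 3 and 42 d replicate 2, and the highest without 57 d replicate 2. At least 2-fold, the ranges were 5263 to 5911, 227 to 1413, 609 to 1942 and 7179 to 7822. Across the 4 ages it was 13493 to 15907, and lists ranged over 11 to 13, 12 to 16, 10 to 16 and 11 to 18. The correlation of the first and last steps ranged from -0.100 to -0.0207, and the spread at 57 d over the next highest from 1.21, without 57 d replicate 2, to 2.09. With only the 6 libraries of the ages compared, 12093, 3232, 498 and 11308 genes were called. Of the 498, 495 were among the 2532, and 358 changed at least 2-fold. The same reduction lowered the count of the whole span and raised the counts of the first and second comparisons. In the main fit the ages share their estimate of spread, while the spread was 0.297 at 57 d and 0.127 to 0.170 at the other ages. The main p-values of the comparisons with 57 d may thus be too small. Whether the spread alone explains the drop was not tested.

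With an estimated inter-gene correlation, 0 lists were called in each of the 4 comparisons (3, 1, 3 and 3 at an unadjusted p under 0.05), against 23, 14, 12 and 27 with fry, which does not compare a list with other genes. The first and last step correlation turned to 0.0438 with an average log2 CPM of at least 2, a fit with fewer genes. Its cause was not tested. Of the named calls, the replicate number as a block ended 1, 3, 6 and 0, DESeq2 ended 1, 2, 1 and 0, and relative log expression factors ended 1, 2, 2 and 0. Depth limits genes with a few counts at 29 d, such as SAG12, to ratios with wide counting intervals.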

Other observations

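The tests of the floral organ genes and of the dawn genes were chosen after the result was seen. The other lists below were written before their members were looked at, but after related genes had been seen to follow these patterns. Genes of sugar starvation, which respond to low carbon, were followed over the ages. All 10 fell from 29 to 35 d, with a median of -1.64 on the log2 scale, 3 rose from 35 to 42 d, and 7 were lower at 57 d than at 29 d. CHYR1, a RING-type ubiquitin ligase gene, fell from 292 ± 39.1 to 24.7 ± 4.41 CPM (SD, n = 3), and ERD5, the proline dehydrogenase gene, from 800 ± 82.6 to 157 ± 33.3. Of 10 genes induced by shade, 6 fell and 1 rose from 29 to 35 d, with a median of -2.26. PAR1, a regulator of shade avoidance, fell from 46.0 ± 10.7 to 0.716 ± 0.451 CPM, BEE1 fell from 12.3 ± 1.64 to 0.643 ± 0.329, and the cytokinin oxidase gene CKX5 rose by 0.81 ± 0.20. From 29 to 57 d, 7 of the 10 fell and 1 rose.

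Of 14 genes known to respond within minutes to touch or wounding, 9 rose and 1 fell from 29 to 35 d, with a median of 1.62. The ERF gene RRTF1 rose from 24.1 ± 15.4 to 532 ± 334 CPM, CYP94B3, a hydroxylase of jasmonoyl-isoleucine, from 3.85 ± 2.28 to 108 ± 49.7, and CML38 from 31.8 ± 18.1 to 386 ± 237. ERF104 fell by 1.17 ± 0.42 on the log2 scale. XTH22, ZAT12, ERF5 and ERF6 changed by -0.12 ± 0.61, -0.06 ± 0.51, -0.43 ± 0.45 and 1.32 ± 0.60, none of them called.

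Of 16 jasmonate genes, 13 rose between 29 and 35 d. Handling only at the 35 d harvest is argued against, since the 14 touch and wound genes changed by a median of 0.14 from 35 to 42 d, where a return would need a fall. Touch or wounding shortly before harvest at 35 d and later may still contribute, as the same genes had a median of 1.62 from 29 to 35 d and 1.5 from 29 to 57 d, with 7 risen and 1 fallen. The list holds CYP94B3, which acts on jasmonoyl-isoleucine, and its relative CYP94C1. They rose by 4.84 ± 0.67 and 4.28 ± 0.42 on the log2 scale from 29 to 35 d. The list is thus not fully independent of the jasmonate genes. Leaf age changed in the same samples and remains open, untested.

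ORE1 and NAP were as high on average at 29 d as at 42 d, and SEN1 and ASN1 were highest at 29 d. A low-sugar or dark state of the 29 d leaves could account for this, given the median of -1.64 in 10 other starvation genes, and so could a shade-type state, given the median of -2.26. Another hour of harvest remains open: of the dawn genes CCA1, LHY, RVE8 and RVE1, 1 of 4 was lower at 35 d and the other 3 higher. Of 13 circadian clock genes, 7 rose and 3 fell from 29 to 35 d. The expectation that all 4 dawn genes move together was not met, but 3 did, so the test cannot decide about another hour. A test chosen after the result was seen does not settle it, and the labels give no harvest hour. Age stays an open explanation, since it changed along with each of these states.

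VGD1, VGDH1, sks13 and AT3G01270 summed to 3.43 to 7.84 CPM at 29 d, 102, 12 and 51.8 in the 35 d replicates 1 to 3, 36.7, 88.2 and 136 at 42 d, and 7.26 to 13.9 at 57 d. Pollen RNA on the leaves is a candidate explanation: of 18 other pollen genes with at least 10 counts, 9 put the libraries of both ages in the same order, against 0.5 by chance, but more than 9 had been asked for. AGP11 reached 5.46 ± 2.97 CPM at 42 d, while TUA1, which the leaf also expresses, stood at 145 to 219 CPM and ANX1 and STP9 did not follow. AP3, PI, AG and AP1 summed to 0.396 CPM on average over the 35 and 42 d libraries, from 6 to 16 counts each. Their sum was 0.184 to 0.410 CPM at 29 d and 0.175 to 0.571 CPM at 57 d. It thus did not set the 35 and 42 d libraries apart, but counts this few give no answer about floral organs. Age remains open for these genes as well.

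At 57 d, replicate 2 held 70.1 CPM of SAG13 against 584 and 134 in replicates 1 and 3, 22.9 of PR1 against 306 and 116, and 67.0 of NAP against 351 and 234.

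Other splits of the samples were tried. For each pair of ages the 6 libraries make 10 splits, too few for a share under 0.05. The real split called 11308 genes from 29 to 35 d against 0 in the highest other, 2240 against 0 from 35 to 42 d, 2532 against 2 from 42 to 57 d, and 12803 against 0 from 29 to 57 d. At least 2-fold, these were 5669 against 0, 1053 against 0, 1085 against 2 and 7404 against 0, so that 1 of the 10 splits, the real one, gave as many. Lists called by camera were 12 against 14, 13 against 16, 13 against 19 and 15 against 18, with 5, 4, 4 and 5 of the 10 splits giving as many. Each other split mixes the ages unequally and keeps part of the difference between them, so it does not decide about the lists. It also puts the difference between the ages into the spread within the groups, which can lower the gene calls. The size of the gap in gene counts is thus partly built in. Across the 4 ages, 1 of 100 splits, the real one, called as many genes, 14719 against 7729 in the highest other. This argues against ages that go with the libraries at random. It cannot tell age from anything else that differed between the ages, or show whether the replicates were separate plants. For the correlation of the first and last steps, 93 of 100 splits gave a value as far from 0 as the real 0.067, the highest other being 0.863. Such splits put differences between ages into both steps, so they do not decide about a value near 0.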
